A study of Trametes versicolor with 3 samples.

How the data were processed

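Trametes versicolor mycelium was taken on day 9 from cultures on PDA, glucose or poplar, and 1 RNA library was sequenced per medium. Per the labels, polyadenylated RNA was enriched with oligo(dT) after DNase treatment, fragmented, copied with random hexamers and sequenced on an Illumina HiSeq instrument. The growth protocol in the labels reads PDA for each sample, in conflict with the source names, and the groups were taken from the source names. With 1 library per group there was no replicate error, no test between groups and no p-value.

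For each library the authors deposited 1 table of gene models with at least 1 read. The deposited counts are uniquely assigned reads per gene model, and each column sum equals the total in the file header. The deposited RPKM values are reads per kilobase of gene model, scaled to that sum of reads, which was checked by recomputing each value. The deposited coverage is the percent of the gene model covered by reads, and it was used only in the closing observations. The gene model length, per the file headers a length in bases, was read as coding length, since nearly all lengths were multiples of 3. The submitters' processing notes name Cufflinks 2.0.1 without its role. The aligner, its settings and the genome build are not given in the sources used here, and gene coordinates were not available. Reads counted as unique leave the levels of close paralogs uncertain. The strand of the libraries is not stated, so antisense and overlapping transcripts cannot be told apart. Genes are named by their protein identifier in the gene model set, with the description the files give. A gene absent from a table was given 0 reads.

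Total reads were 2.85 M in the PDA library, 2.68 M in the glucose library and 2.80 M in the poplar library, with median counts of 58, 55 and 58 per listed gene model. A floor of 3 reads on a 1 kb gene model came to 1.05 RPKM in the PDA library, 1.12 in the glucose library and 1.07 in the poplar library.

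For each pair of libraries the log2 ratio of RPKM plus a pseudocount of 1 was computed. A gene counted as measured with an RPKM of at least 1 in either library, and as higher or lower at a ratio of at least 2 on that scale. Folds of single genes are plain RPKM ratios with the exact conditional (Clopper-Pearson) 95% interval of the count ratio. Where a library had 0 reads the fold was computed against 3 reads and given with the exact 95% limit, which is the lower bound. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

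There were 24 gene lists: class II peroxidases, laccases, DyP and heme-thiolate peroxidases, hydrogen peroxide-producing oxidases, cellulases, beta-glucosidases, LPMOs and cellobiose dehydrogenase, hemicellulases, pectinases, starch-degrading enzymes, cytochrome P450s, aromatic and xenobiotic conversion, sugar transporters including general substrate transporters, glycolysis including phosphoglycerate mutase-like genes, glyoxylate, oxalate and formate metabolism, cytosolic ribosomal proteins, hydrophobins, heat shock proteins and chaperones, proteases, fungal cell wall synthesis and turnover, antioxidant defence, nitrogen and peptide uptake, fruiting and mating, and plant transcripts. Members were found by text patterns on the protein description and the KEGG names, and a gene can be in several lists. Each list was summarised by the median log2 ratio of its measured members. The counting interval of the median came from 1000 Poisson draws of the counts. Its percentile came from 10000 random lists of equal size matched on expression in 20 bins, for lists of at least 3 measured members. The comparisons, thresholds, lists, alternatives and the rule for named genes were fixed before the data were examined. That each pattern was applied to every annotation name separately was fixed after the annotations were seen.

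Named genes were the 5 highest and 5 lowest log2 ratios of each comparison, up to 3 members of each of the first 9 lists and 1 of each other list with the largest ratio of at least 2-fold, the 10 highest RPKM values of each library, and up to 10 genes at least 4-fold above and 10 at least 4-fold below both other media in the poplar library. An RPKM of at least 10 in the higher library was required for genes chosen by ratio. Genes outside this rule are said to have been chosen after their values were seen.

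The procedure was tested on simulated data with 200 genes changed 4-fold, all with an expected count of at least 50 reads. Of these, 100% were recovered between poplar and glucose, 100% between poplar and PDA and 99.5% between glucose and PDA. Recovery in genes with fewer reads was not measured. The counting interval covered the simulated ratio in 96.5%, 96.7% and 96.6% of genes in these comparisons. Of 40 lists drawn from unchanged genes in each, 92.5%, 95% and 90% had a median inside the central 95% of random lists. Alternatives were pseudocounts of 0.1 and 5, a minimum RPKM of 10 and no minimum, a 4-fold threshold, rescaling by the median of ratios, rescaling without the 50 highest genes, ratios from counts scaled by total count, and ratios of summed RPKM in place of medians. The median-of-ratios factors were 0.975 for the PDA library, 0.983 for the glucose library and 1.05 for the poplar library. Alternatives added after the data were seen were the requirement that the counting interval exclude 1, patterns on the joined names, descriptions alone, and leaving out 7 abundant short gene models. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.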

Results

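Transcript levels of Trametes versicolor, a white-rot fungus that degrades lignin as well as the polysaccharides of wood, were measured by RNA sequencing in mycelium grown for 9 days on 3 media. One medium was PDA, the usual abbreviation of potato dextrose agar, a rich medium for fungal culture. Another had glucose as its carbon source, and the remaining one was made with poplar. The mycelial mat had reached 4 cm. Each medium was represented by 1 library, so no difference between media has a replicate check, and every value describes these libraries. The PDA library held 2.85 M uniquely assigned reads, the glucose library 2.68 M and the poplar library 2.80 M. These reads fell on 10871 gene models in the PDA library, 10979 in the glucose library and 11101 in the poplar library, of which 8429, 8550 and 8702 had at least 10 reads. On a gene model of 1 kb, 1 read was worth 0.351 RPKM in the PDA library, 0.373 in the glucose library and 0.357 in the poplar library. Folds are ratios of RPKM, followed in parentheses by the 95% exact counting interval, which covers counting error only. Genes were called higher or lower at a 2-fold difference of RPKM plus 1.

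The comparison of the poplar and glucose libraries addressed how the transcript profile on wood differed from that on a simple sugar. Most lignin peroxidase transcripts were higher in the poplar library, whereas cellulase and lytic polysaccharide monooxygenase (LPMO) transcripts were lower in their medians and sums. Of the 24 measured members of the class II peroxidase list, 9 were at least 2-fold higher and 6 at least 2-fold lower. Their median log2 ratio was 0.34 (counting interval 0.24 to 0.53). Class II peroxidases are secreted heme enzymes that oxidise lignin, but members were found by name only. Of them, 2 also matched the antioxidant defence list. With patterns on the joined names 7 were higher and 4 lower of 17, with a median of 0.27. Of the 35 measured cellulases, 2 were higher and 13 lower, with a median of −0.49 (−0.69 to −0.38). Only 11 of this list's 36 members matched by description, and the others entered through KEGG names. With descriptions alone 1 was higher and 6 lower of 11, with a median of −1.01. The list of LPMOs, which cleave cellulose oxidatively, and cellobiose dehydrogenase had 7 measured genes. Of these, 0 were higher and 4 lower, with a median of −1.17 (−1.23 to −0.63). The peroxidase median lay at percentile 99.5 of 10000 random lists matched on expression, the LPMO median at percentile 0.01, and the cellulase median below that of each random list. Over all 10636 measured genes, 861 were higher and 884 lower in the poplar library, with a median log2 ratio of 0.08. The counting interval excluded a ratio of 1 for 586 of the higher and 652 of the lower genes. In simulated libraries of this depth, counting noise alone moved 4.14% of unchanged genes past the 2-fold threshold.

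Genes described as lignin peroxidase or ligninase were set beside those described as manganese peroxidase. This grouping by name was made after the values were seen. Both groups were drawn from all gene models and do not divide the class II list. Together they count more genes as higher in the poplar library than the list's 9. The manganese peroxidase group therefore reaches outside the list or shares genes with the other group. Of the 11 genes with a lignin peroxidase name, 8 were higher and 0 lower in the poplar library, with a median log2 ratio of 1.83. Their summed RPKM was 4011 in the poplar library and 1529 in the glucose library. Of the 10 genes with a manganese peroxidase name, 2 were higher and 4 lower, with a median of −0.35, although their summed RPKM was also higher in the poplar library, at 951 against 457. Genes described as manganese-repressed were left out of this group. Among them was Trave1_26509, which was lower in the poplar library than in the glucose library and is not in these sums. The lignin peroxidase Trave1_134496 measured 299 RPKM in the poplar library against 11.3 in the glucose library, 26.3-fold higher (18.6 to 38.5). Trave1_43846, also a lignin peroxidase, was 22.1-fold higher (12.1 to 44.8), and Trave1_52603 was 15.6-fold higher (11.2 to 22.4). Ligninase C, Trave1_115214, had the highest level of the list in the poplar library, at 1965 RPKM, and was 3.56-fold higher (3.37 to 3.76). In the other direction, the manganese peroxidase Trave1_45167 measured 13.5 RPKM in the poplar library and 98.3 in the glucose library, 7.29-fold lower (5.24 to 10.4). A gene described only as peroxidase and therefore outside the list, Trave1_43747, was 52.9-fold higher (29.3 to 106), at 198 RPKM against 3.74.

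**Figure D1:**
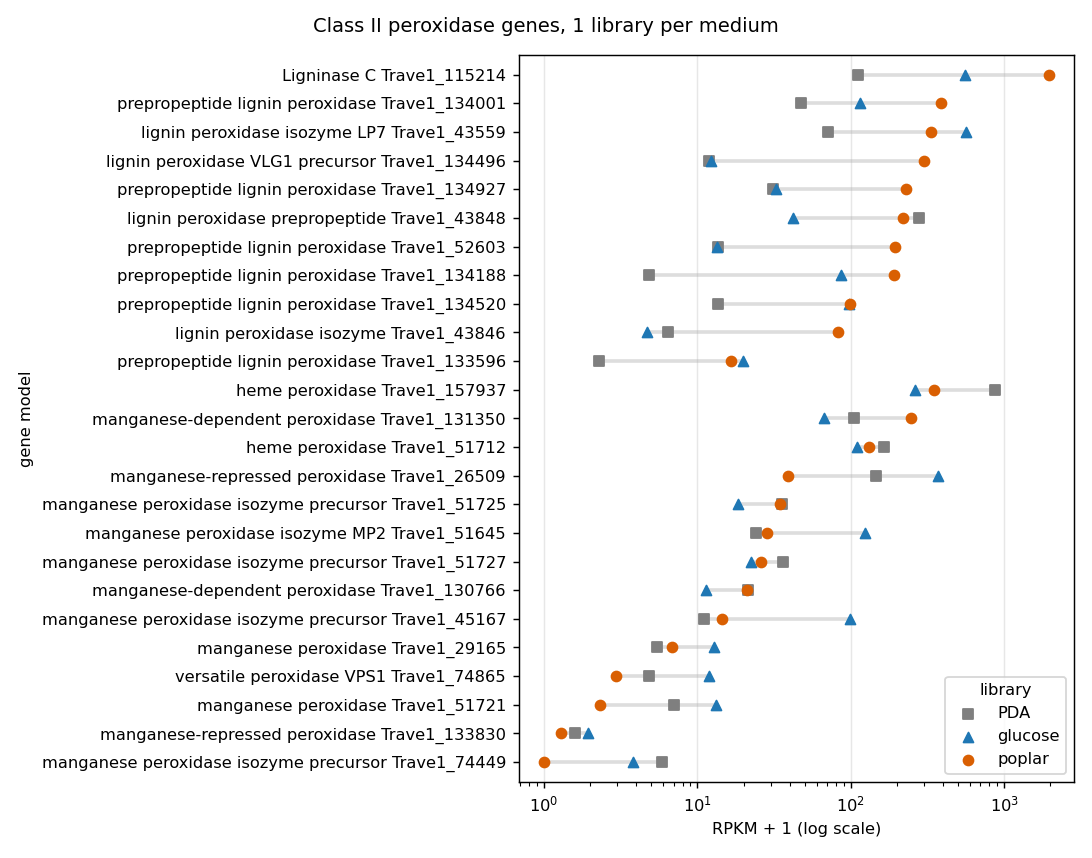
RPKM plus 1, on a log axis, of each gene model in the class II peroxidase list in the PDA (square), glucose (triangle) and poplar (circle) libraries, with 1 library per medium and lignin peroxidase names at the top. A grey bar joins the lowest and highest library, and ligninase C reached 1965 RPKM in the poplar library against 553 in the glucose library.

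The cellulase transcripts summed to 13652 RPKM in the poplar library and 27667 in the glucose library, 2.03-fold lower. Cellobiohydrolase I, which releases cellobiose from cellulose chain ends, was 2.56-fold lower (2.44 to 2.68) for Trave1_111060, at 607 RPKM against 1552. Cellobiohydrolase II, Trave1_64096, was 2.35-fold lower (2.28 to 2.42), at 1646 against 3868 RPKM. The members of the cellulase list with the lowest ratios were the cellulose-growth-specific protein Trave1_43328, 11.3-fold lower (8.57 to 15.2), and Trave1_148097, annotated as an endoglucanase, 7.37-fold lower (6.70 to 8.12). The description of Trave1_43328 did not match the cellulase patterns, and it is in the list through its KEGG names alone. The 2 cellulases that were higher were Trave1_53450, annotated as an endoglucanase, which had 47 reads in the poplar library and 2 in the glucose library and was 22.5-fold higher (5.89 to 191), and another cellobiohydrolase I gene, Trave1_124636, with a log2 ratio of 1.51 at 893 against 313 RPKM. Trave1_124636 was chosen after its values were seen. Of the LPMOs, listed as glycoside hydrolase family 61, Trave1_34454 was 7.26-fold lower (6.49 to 8.14) and Trave1_162999 was 2.25-fold lower (2.15 to 2.36). Cellobiose dehydrogenase, Trave1_73866, was 2.54-fold lower (2.27 to 2.85). The cellulase and LPMO lists shared 4 genes, Trave1_34454, Trave1_45462, Trave1_51274 and Trave1_69299. The results of these lists are therefore not those of separate enzyme classes.

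**Figure D2:**
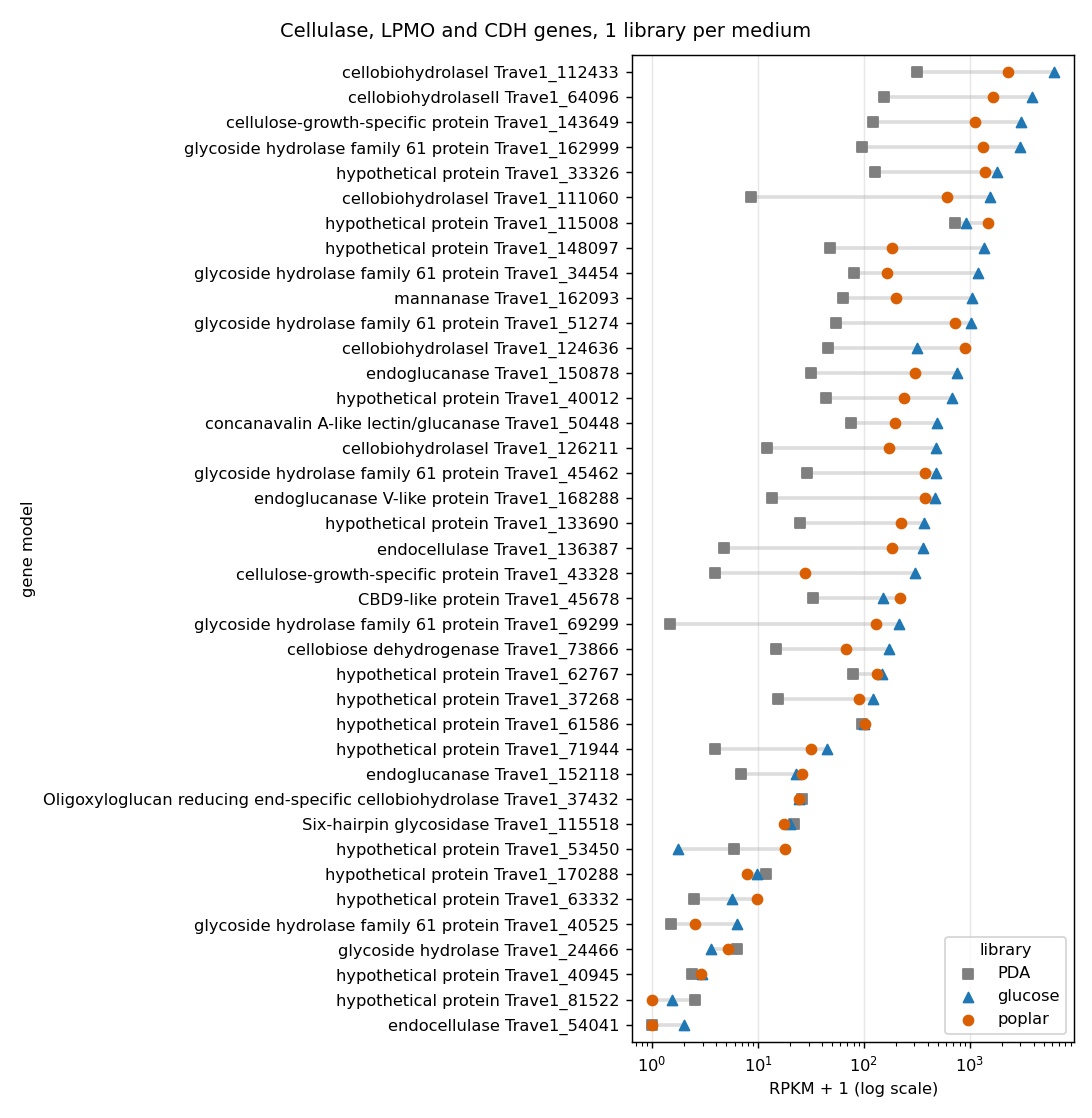
RPKM plus 1, on a log axis, of each gene model in the cellulase list and in the list of LPMOs and cellobiose dehydrogenase (CDH) in the PDA (square), glucose (triangle) and poplar (circle) libraries, with 1 library per medium. A grey bar joins the lowest and highest library, and cellobiohydrolase I Trave1_111060 measured 7.68, 1552 and 607 RPKM in that order.

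Of 37 measured hemicellulases, 6 were higher and 9 lower in the poplar library than in the glucose library, with a median log2 ratio of −0.05 (−0.29 to 0.03) at percentile 8.95. Their summed RPKM was 1.95-fold lower, at 6000.4 against 11699, and the median over genes of at least 10 RPKM was −0.45. Trave1_114254, annotated as an alpha-galactosidase, was 6.88-fold lower (6.20 to 7.64), and the acetyl xylan esterase Trave1_162219 was 6.47-fold lower (5.61 to 7.50). The endo-beta-1,4-glucanase Trave1_34218, which KEGG names a xylanase, was 8.46-fold higher (5.25 to 14.4). The wording of its description did not match the cellulase patterns, so it is not counted among the cellulases. Of 15 pectinases, 2 were higher and 3 lower, with a median of 0.38 (0.24 to 0.72) at percentile 99.3, although their summed RPKM was lower, with a log2 ratio of −0.12. Endo-polygalacturonase Trave1_172131 was 8.75-fold higher (4.01 to 22.6), and rhamnogalacturonase Trave1_73205 was 2.38-fold lower (2.08 to 2.73). Of 16 beta-glucosidases, 2 were higher and 1 lower, with a median of −0.23 (−0.36 to 0.03) and a summed RPKM of 2605 against 4749.9. This list and the hemicellulases also hold cellobiohydrolase II, Trave1_64096, through its KEGG names, and without it the beta-glucosidase sums were 959 against 882 and the hemicellulase sums 4354 against 7831. The hypothetical protein Trave1_133690, whose KEGG names include a cellobiosidase and an endoglucanase, stays in these sums of both lists. It measured 224 RPKM in the poplar library against 372 in the glucose library. The beta-glucosidase Trave1_55904 was 4.04-fold higher (3.67 to 4.46). None of the 5 laccases was higher and 1 was lower, laccase I Trave1_68293, which was 4.91-fold lower (3.35 to 7.38); the list's median was −0.11. Of 37 hydrogen peroxide-producing oxidases, 4 were higher and 4 lower, with a median of −0.07 at percentile 5.17. Their summed RPKM went the other way, at 9217 in the poplar library against 5809 in the glucose library, a log2 ratio of 0.67, and pyranose 2-oxidase Trave1_174991 was 2.33-fold higher (2.26 to 2.41). The GMC oxidoreductase Trave1_163334 was 7.04-fold higher (4.96 to 10.3), and the aryl-alcohol oxidase-like gene Trave1_176418 was 3.31-fold lower (2.43 to 4.56). Neither of the 2 genes for DyP and heme-thiolate peroxidases reached a 2-fold difference, and their median was −0.31.

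Of 39 starch-degrading enzymes, 7 were higher and 4 lower in the poplar library than in the glucose library, with a median log2 ratio of 0.28, and glucoamylase Trave1_37627 was 8.68-fold lower (7.40 to 10.2). By description only 12 of the 45 members in the files matched, with 1 higher, 1 lower and a median of 0.21. Of 112 genes of aromatic and xenobiotic conversion, 10 were higher and 21 lower, and the median of −0.21 (−0.34 to −0.06) lay below that of each random list. Only 26 of this list's 123 members matched by description, and the others entered through KEGG names. With descriptions alone 2 were higher and 4 lower of 23, with a median of −0.23. Of 161 cytochrome P450s, 20 were higher and 21 lower, with a median of −0.08 (−0.15 to 0.02) that became positive, at 0.17, over genes of at least 10 RPKM. The P450 Trave1_46544 was 20.4-fold higher (13.1 to 33.8). Of 146 members of the transporter list, 141 were described as general substrate transporters, and of the 139 measured, 10 were higher and 12 lower, and the general substrate transporter Trave1_51916 was 10.8-fold higher (7.94 to 14.96). Of 22 genes of glyoxylate, oxalate and formate metabolism, 1 was higher and 4 lower, oxalate decarboxylase Trave1_60985 by 7.32-fold (4.87 to 11.4). Antioxidant defence had 1 higher and 5 lower of 37, with a median of −0.16 at percentile 0.775. Hydrophobins, the small surface proteins of aerial hyphae, had 10 higher and 7 lower of 34, with hydrophobin 2 Trave1_46553 higher by 13.1-fold (6.67 to 29.3). The hydrophobin median was nevertheless −0.15 (−0.43 to 0.19) at percentile 1.24, and the log2 ratio of their summed RPKM was −0.18. The glycolysis list had 1 higher and 4 lower of 31, but 11 of its members were phosphoglycerate mutase-like genes that KEGG names acid phosphatases. With patterns on the joined names it had 0 higher and 1 lower of 20. Cytosolic ribosomal proteins had 1 higher and 0 lower of 104, with a median of 0.06 as deposited and of −0.03 after median-of-ratios scaling. Heat shock proteins and chaperones had 6 higher and 6 lower of 73, proteases 11 and 11 of 93, fungal cell wall genes 5 and 5 of 49, nitrogen and peptide uptake 4 and 4 of 50, and fruiting and mating 4 and 4 of 16. No gene model matched the list of plant transcripts, so the check for RNA of the wood itself had no members.

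The genes with the largest differences between the poplar and glucose libraries mostly lacked a functional description. Trave1_51756 had 590 reads in the poplar library and 11 in the glucose library, 51.3-fold higher (28.5 to 103), and Trave1_46332 was 50.8-fold higher (25.6 to 118). Trave1_65334 was lower, with 1363 RPKM in the glucose library and 16.8 in the poplar library, 81.1-fold lower (54.3 to 127). The small heat shock protein Trave1_127684 had 78 reads in the glucose library and 0 in the poplar library. It was 27.2-fold lower against a floor of 3 reads, and its exact 95% limit was at least 21.6-fold lower. The aspartic proteinase Trave1_37643 had 3 reads in the poplar library against 146, 50.9-fold lower (17.1 to 249.6).

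Against the PDA library, the poplar library was higher in most lignin peroxidases and most enzymes of cellulose degradation. Of 35 cellulases, 27 were higher and 1 was lower, with a median log2 ratio of 2.55 (2.30 to 2.81), and of 7 LPMOs and cellobiose dehydrogenase, 6 were higher and 0 lower, with a median of 3.72 (3.39 to 3.83). Of 24 class II peroxidases, 11 were higher and 4 lower, with a median of 0.36 (0.14 to 0.91) at percentile 99.2; matching the list's patterns to the joined annotation text gave a median of 2.23. Of the 11 genes with a lignin peroxidase name, 10 were higher and 0 lower, with a median of 3.03. Of the 10 with a manganese peroxidase name, 2 were higher and 2 lower, with a median of 0.11. Hemicellulases had 19 higher and 3 lower of 37, with a median of 1.08 (0.92 to 1.27). The medians of the cellulases, LPMOs and hemicellulases exceeded those of each of the 10000 random lists. Over all 10506 measured genes, 1136 were higher and 537 lower in the poplar library, with a median log2 ratio of 0.09, and the counting interval excluded a ratio of 1 for 822 and 369 of them. In simulated libraries, counting noise moved 4.06% of unchanged genes past the threshold.

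Cellobiohydrolase I Trave1_111060 had 30 reads in the PDA library and 2331 in the poplar library, 79.1-fold higher (55.3 to 118). Endocellulase Trave1_136387 was 47.7-fold higher (23.98 to 111), and the family 61 LPMO Trave1_69299, with 1 read in the PDA library and 266 in the poplar library, was 271-fold higher (48.2 to 10738). The LPMOs Trave1_162999 and Trave1_51274 were 14.0-fold (12.03 to 16.3) and 13.8-fold (11.5 to 16.7) higher. The lignin peroxidase Trave1_134188 was 49.6-fold higher (28.2 to 96.5), Trave1_134496 was 27.2-fold higher (19.3 to 39.5), and ligninase C, Trave1_115214, was 17.7-fold higher (15.9 to 19.8). Among the hemicellulases, Trave1_34218 was 21.4-fold higher (10.6 to 50.3), and Trave1_145163, annotated as a xylanase, was 12.3-fold higher (9.12 to 17.0). Of 15 pectinases, 7 were higher and 0 lower, with a median log2 ratio of 0.89, and rhamnogalacturonan hydrolase Trave1_62920 was 42.1-fold higher (19.1 to 116). Of 15 beta-glucosidases, 7 were higher and 0 lower, with a median of 0.97, among them Trave1_68827, which was 8.63-fold higher (6.03 to 12.7). Of the 5 laccases, laccase 5 Trave1_146502 alone was higher, by 2.11-fold (1.51 to 2.99), and the median was 0.52.

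Hydrogen peroxide-producing oxidases had 12 higher and 2 lower of 37 in the poplar library against PDA, with a median log2 ratio of 0.60 (0.24 to 0.71). Their summed RPKM went the other way, with a log2 ratio of −0.26, and pyranose 2-oxidase Trave1_174991, which oxidises sugars and yields hydrogen peroxide, measured 2316 RPKM in the poplar library and 7639 in the PDA library, 3.30-fold lower (3.23 to 3.37). Glyoxal oxidase Trave1_118536 was 5.93-fold higher (4.92 to 7.20). Catalase Trave1_152668, which breaks down hydrogen peroxide, was 2.68-fold higher (2.60 to 2.76), at 3710 against 1385 RPKM, in a list of antioxidant defence in which 4 of 38 were higher and 3 lower. NAD-dependent formate dehydrogenase Trave1_56661 was 3.69-fold higher (3.46 to 3.94), while its list of glyoxylate, oxalate and formate metabolism had 4 higher and 2 lower of 22. Of the 2 DyP and heme-thiolate peroxidases, 0 were higher and 1 lower, the Dyp-type peroxidase Trave1_49144, which was 4.22-fold lower (3.02 to 5.998).

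Sugar and general substrate transporters were more often higher than lower in the poplar library against PDA, at 29 against 9 of 141, with a median log2 ratio of 0.22 (0.17 to 0.34) at percentile 98.2. Starch-degrading enzymes had 10 higher and 1 lower of 38, with a median of 0.35 (0.25 to 0.63), and glucoamylase Trave1_37627 was 6.70-fold higher (4.42 to 10.5). With descriptions alone 3 were higher and 0 lower of 12, with a median of 0.20. Fruiting and mating genes had 7 higher and 4 lower of 16, with a median of 0.76 (0.45 to 0.97), and the pheromone gene Trave1_45033 was 4.85-fold higher (3.74 to 6.35). Cytochrome P450s had 15 higher and 28 lower of 156, with a median of −0.15 (−0.23 to −0.08). None of the 104 cytosolic ribosomal proteins passed the 2-fold threshold, yet their median of −0.25 (−0.27 to −0.22) and that of the P450s lay below those of each random list. Hydrophobins had 5 higher and 7 lower of 32, including Trave1_130087, which was 14.8-fold lower (11.9 to 18.7). Fungal cell wall genes had 6 higher and 0 lower of 49, with a median of 0.28 (0.23 to 0.33). Nitrogen and peptide uptake had 6 higher and 0 lower of 50, proteases 10 and 10 of 91, heat shock proteins and chaperones 0 and 4 of 73, the glycolysis list 3 and 0 of 31, or 1 and 0 of 20 with joined names, and aromatic and xenobiotic conversion 20 and 14 of 113. The metalloprotease Trave1_164315 was 32.3-fold higher (21.0 to 52.5). On the log2 scale with the pseudocount, the highest ratio was that of Trave1_51756, 150.2-fold higher in RPKM (58.4 to 553), and the lowest that of Trave1_48551, 34.2-fold lower (18.4 to 71.9).

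Between the 2 libraries labelled as media without wood, the glucose library was higher than the PDA library in most enzymes of cellulose degradation. An exchange of the glucose and poplar labels, which is left open below, would swap this comparison with that of poplar and PDA. Of 36 cellulases, 26 were higher and 1 lower, with a median log2 ratio of 3.67 (3.34 to 3.87), and all 7 LPMOs and cellobiose dehydrogenase were higher, with a median of 4.07 (3.83 to 4.34). Cellobiohydrolase I Trave1_111060 was 202-fold higher (142 to 300.01) and cellobiohydrolase II, Trave1_64096, was 25.4-fold higher (23.4 to 27.6). Summed over their lists, cellulase RPKM was 12.2-fold higher and LPMO and cellobiose dehydrogenase RPKM 22.5-fold higher in the glucose library. Hemicellulases had 21 higher and 4 lower of 37, with a median of 1.08 (0.93 to 1.40), pectinases 9 and 0 of 15, with a median of 1.13, and beta-glucosidases 7 and 1 of 16, with a median of 0.82. Class II peroxidases had 11 higher and 2 lower of 24, with a median of 0.49 (0.21 to 0.87) at percentile 99.8. Over all 10487 measured genes, 1334 were higher and 684 lower, with a median log2 ratio of 0.01, and the counting interval excluded a ratio of 1 for 1021 and 496 of them. In simulated libraries, counting noise moved 3.82% of unchanged genes past the threshold.

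The family 61 LPMO Trave1_69299 had the largest plain ratio of these enzymes, 448-fold higher in the glucose library (80.0 to 17743). This ratio rests on 421 reads against 1, and its interval holds the whole interval of cellobiohydrolase I Trave1_111060. The cellulose-growth-specific protein Trave1_43328 was 106-fold higher (48.2 to 289), Trave1_145163 was 74.01-fold higher (55.4 to 101), and glucoamylase Trave1_37627 was 58.1-fold higher (39.5 to 89.3). Of the 11 genes with a lignin peroxidase name, 6 were higher and 1 lower, with a median log2 ratio of 1.27, and of the 10 with a manganese peroxidase name, 3 were higher and 1 lower, with a median of −0.64. The lignin peroxidase Trave1_134188 was 22.1-fold higher (12.4 to 43.3), and the manganese peroxidase Trave1_45167 was 9.82-fold higher (6.77 to 14.7). The peroxidase Trave1_43747 was 34.3-fold lower (19.0 to 69.3). Laccases had 2 higher and 0 lower of 5, with a median log2 ratio of 0.88, and laccase I was 7.50-fold higher (4.78 to 12.3). Hydrogen peroxide-producing oxidases had 15 higher and 3 lower of 37, with a median of 0.67, while their summed RPKM had a log2 ratio of −0.92, and pyranose 2-oxidase Trave1_174991 was 7.70-fold lower (7.48 to 7.93). Catalase Trave1_152668 was 2.66-fold higher (2.58 to 2.74), and formate dehydrogenase Trave1_56661 was 5.58-fold higher (5.25 to 5.94). Cytochrome P450s went both ways, with 28 higher and 37 lower of 161, and Trave1_46544 was 70.5-fold lower (45.5 to 116). Hydrophobins had 10 higher and 11 lower of 34, with a median of −0.42 (−0.79 to −0.04). Cytosolic ribosomal proteins had 0 higher and 3 lower of 104, with a median of −0.32 (−0.34 to −0.28). Sugar and general substrate transporters had 33 higher and 8 lower of 140, aromatic and xenobiotic conversion 31 and 12 of 111, antioxidant defence 10 and 2 of 37, and proteases 18 and 13 of 89. Starch-degrading enzymes had 9 higher and 3 lower of 34, with a median of −0.01 and a log2 ratio of summed RPKM of 0.39. The glycolysis list had 7 higher and 1 lower of 31, or 2 and 0 of 20 with joined names, glyoxylate, oxalate and formate metabolism 4 and 2 of 21, and heat shock proteins and chaperones 5 and 4 of 72. Fungal cell wall genes had 11 higher and 3 lower of 49, nitrogen and peptide uptake 8 and 3 of 50, and fruiting and mating 2 and 2 of 16. Of the 2 DyP and heme-thiolate peroxidases, 0 were higher and 1 lower, Trave1_49144, by 3.23-fold (2.38 to 4.44).

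**Figure D3:**
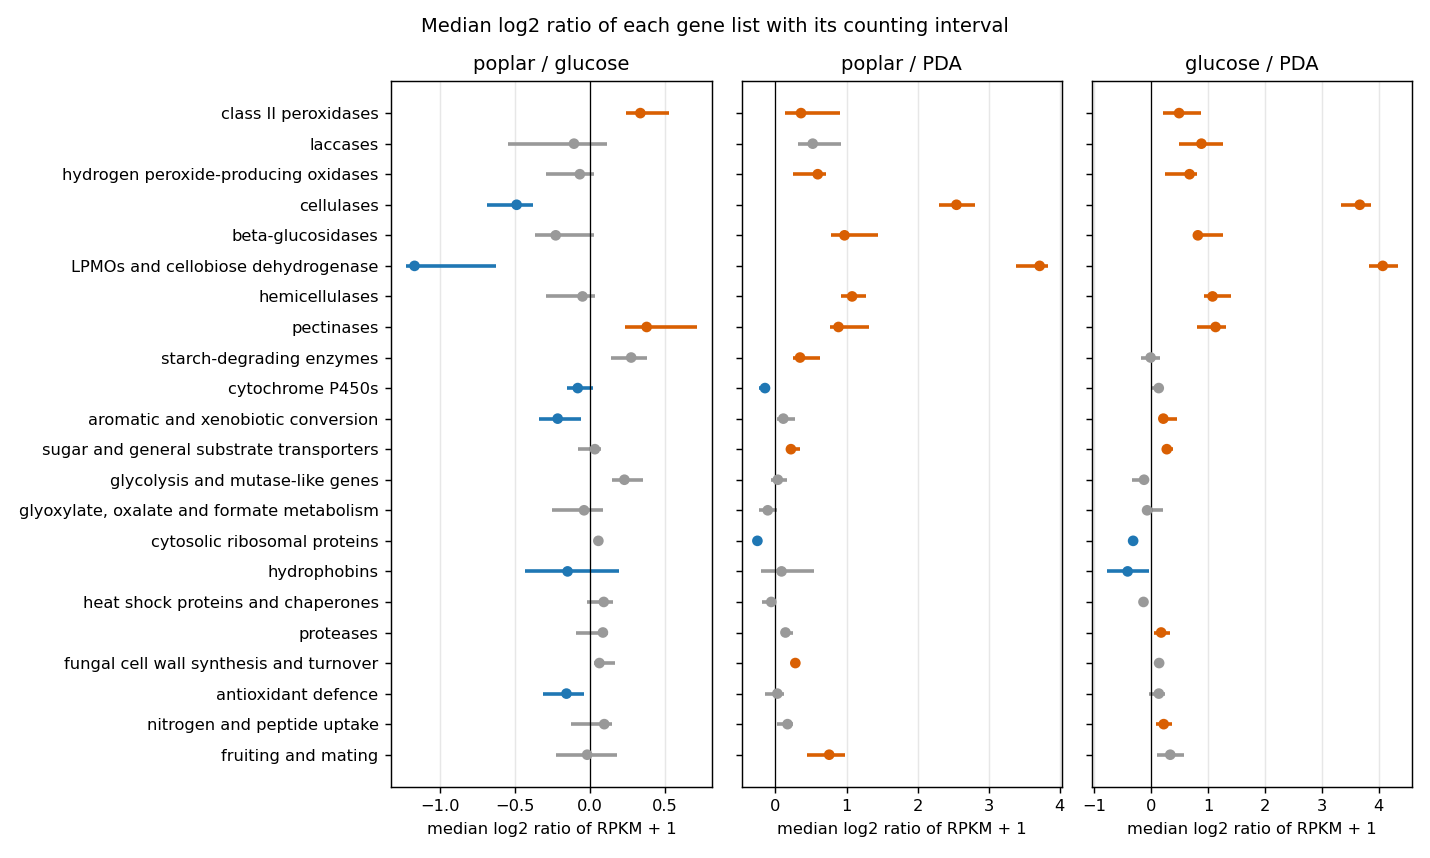
Median log2 ratio of RPKM plus 1 over the measured members of each gene list (points) with its 95% counting interval (bars) for poplar over glucose, poplar over PDA and glucose over PDA, 1 library per medium, on x axes of different ranges. Orange marks medians above and blue medians below the central 95% of the random lists, and the cellulase medians were −0.49, 2.55 and 3.67 in that order.

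Genes set apart in the poplar library from both other media included lignin peroxidases. Of 10386 genes measured in both comparisons, 351 were at least 2-fold higher and 204 at least 2-fold lower in the poplar library than in each of the other libraries. The lignin peroxidases Trave1_134496, Trave1_52603 and Trave1_43846 were at least 4-fold higher than in both, as were hydrophobin 2 Trave1_46553 and the xylanase-annotated Trave1_34218. At the 4-fold level there were 52 higher genes and 14 lower genes. Trave1_51756 was the most extreme of the higher genes, at 590.3 RPKM in the poplar library against 11.5 in the glucose library and 3.93 in the PDA library. Trave1_44446 had 47 reads in the poplar library, 1 in the glucose library and 0 in the PDA library. It was 44.96-fold higher (7.68 to 1813) than in the glucose library. Against a floor of 3 reads in the PDA library it was 15.95-fold higher, and its exact 95% limit was at least 12.5-fold higher. Among the lower genes, the alpha/beta-hydrolase Trave1_163296 was 10.2-fold lower (7.81 to 13.5) than in the glucose library and 7.10-fold lower (5.41 to 9.47) than in the PDA library, and the S53 family protease Trave1_53903 was 5.92-fold (2.89 to 13.7) and 8.73-fold (4.38 to 19.8) lower. Both ratios share the poplar library, so counting noise in it raises the overlap. In 100 simulations without any difference, counting noise gave a mean of 67.2 higher and 78.2 lower genes and at most 91 and 103, and independent lists of the observed sizes would share 94.2 higher and 33.6 lower genes. How much of the excess over these numbers comes from the shared library is open, since it cannot be split. With the counting intervals of both ratios excluding 1, the numbers were 214 and 121.

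The most abundant transcripts were dominated by short gene models. Trave1_137702, of 168 bases, measured 90902 RPKM in the PDA library, 75825 in the glucose library and 44262 in the poplar library. It belonged to 7 gene models of 150 to 366 bases that took 4.80%, 4.21% and 2.70% of all reads in these libraries. The hydrophobin Trave1_129761 measured 16185 RPKM there, 5166 in the glucose library and 3881 in the poplar library, 4.17-fold lower (4.02 to 4.32) in the last than in the PDA library. Trave1_28784 measured 15523 RPKM in the PDA library and 10726 in the poplar library but 2845 in the glucose library, 5.46-fold lower (5.27 to 5.64) than in the PDA library. Trave1_109473 had its highest level in the glucose library, at 12921 RPKM against 6454 in the PDA library and 6099 in the poplar library. The 50 gene models with the most reads in each library took 24.4% of the reads in the PDA library, 20.7% in the glucose library and 19.7% in the poplar library.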

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

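The tests of a few genes taking most of the counts, of a common source for 7 short gene models and of reads shared between paralogs were chosen only after their results were seen.

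The coverage of gene models by reads was used in no comparison, and it showed 8 gene models with at least 1000 reads over the 3 libraries but under 50% of their length covered in each library. They included a hydrophobin, Trave1_30748, with a highest coverage of 25.8%, and a glycoside hydrolase, Trave1_30243, with 34.7%. The transaldolases Trave1_30705 and Trave1_32869 reached 48.4% and 36.3%. Trave1_137697, with 45.5%, had the most reads of the 8 and is also 1 of the 7 short gene models described below. These genes were chosen after their values were seen, and no explanation of their coverage was tested.

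Cellulases and LPMOs were lower in the poplar library than in the glucose library, with a median log2 ratio of −0.61 over 38 members. Counts taken by a few genes would lower all other genes alike, but 10549 measured genes outside these lists and the 50 most abundant had a median of 0.082 (counting interval 0.068 to 0.085), which argues against it as the cause. Among 3435 other genes of like length the median was 0.053, which argues against length bias. An exchange of the glucose and poplar labels could also produce the pattern and stays open: the median of −0.14 over 27 genes chosen as targets of glucose repression cannot bear on it, since most were acetyl-CoA synthetase-like genes that KEGG mostly names as other enzymes, and the log2 ratios of malate synthase Trave1_56596 (−0.61), phosphoenolpyruvate carboxykinase Trave1_69551 (0.15), fructose-1,6-bisphosphatase Trave1_70842 (−0.03) and acetate-CoA ligase Trave1_67770 (−0.14) went both ways. The difference in growth medium also stays open and was not tested, since each medium has 1 library.

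Among the 12 gene models with the highest mean RPKM, 7 short ones with 24 or 96 in their model names were all lower in the poplar library, with a median log2 ratio of −0.74 against PDA. Other models of at most 300 bases had a median of −0.068 (−0.11 to 0.02; 251 models), which argues against a bias against short models as the cause. Reads of a common source, such as ribosomal RNA, stay open: the log2 ratios of the 7 models had an SD of 0.14 over PDA and 0.09 over glucose, but the limit for this SD was set after the values were seen. The ratios over PDA ran from −1.04 for Trave1_137702, 2.05-fold lower (2.02 to 2.09), to −0.61 for Trave1_137697, 1.52-fold lower (1.47 to 1.58), so they differed by more than counting error. No biological explanation was tested.

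Of the 11 genes with lignin peroxidase names, 8 were at least 2-fold higher and 0 at least 2-fold lower in the poplar library than in the glucose library. Had reads only moved between paralogs, the summed RPKM of the 24 measured class II peroxidases would be similar in both libraries. Its log2 ratio was 0.89, which argues against such movement as the whole cause. Reads left out because paralogs share them do not enter this sum, so it cannot bear on their loss. Without ligninase C, the most abundant copy, the summed ratio of the other 10 genes was 1.07 against 1.39 with it, which argues against 1 dominating copy. A response to the medium may underlie the pattern as a hypothesis, found and tested on the same libraries, and an exchange of the glucose and poplar labels remains open here as well.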

How the results depend on the processing

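The counting-interval requirement, the joined names, the descriptions alone and the analysis without 7 short gene models were chosen only after the results were seen. No paired analysis was possible because each group has 1 library.

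With a pseudocount of 5, 321 genes were higher and 468 lower between poplar and glucose, 505 and 248 between poplar and PDA, 735 and 330 between glucose and PDA, and 123 and 72 in poplar against both media. At a minimum RPKM of 10 these counts were 420 and 547, 617 and 316, 864 and 428, and 162 and 99, with fewer genes tested. At 4-fold they were 136 and 194, 219 and 97, 334 and 142, and 52 and 14. Requiring counting intervals that exclude 1 left 214 and 121 against both media. Across the alternatives tried, 23 of the counts of higher genes and 23 of those of lower genes stayed within 1.5 times the main count, and 13 of each moved further. Running with no minimum tested nothing and is not counted, since with a pseudocount of 1 no gene under 1 RPKM in both libraries can pass 2-fold.

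For class II peroxidases, summed RPKM gave a log2 ratio of 0.89 between poplar and glucose and 1.29 between poplar and PDA. A minimum RPKM of 10 gave 1.74 between poplar and PDA and 1.07 between glucose and PDA, and joined names gave 2.23 and 1.27. For cellulases between poplar and glucose, summed RPKM gave −1.02 and descriptions alone −1.01. Between poplar and PDA they had 2.18 with a pseudocount of 5, 2.85 at a minimum RPKM of 10 and 3.62 from descriptions alone, and between glucose and PDA 3.20, 3.92 and 4.57, with 2.87 from joined names. LPMOs and cellobiose dehydrogenase had −1.26 between poplar and glucose after median-of-ratios scaling, and summed RPKM gave 3.37 between poplar and PDA and 4.49 between glucose and PDA. Hemicellulases between poplar and glucose had −0.45 at a minimum RPKM of 10 and −0.96 summed. Between poplar and PDA they had 0.92 with a pseudocount of 5 and 1.80 summed, and between glucose and PDA 0.76 with a pseudocount of 5, 1.85 at a minimum RPKM of 10 and 2.77 summed. The direction held in each of these, and the cause was not tested. In all, 71 medians of these lists under the alternatives stayed within the counting interval and the 25 given here moved.

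Where the median lay outside the central 95% of the random lists, a change of sign was counted as reversed; there were 7, and the cause was not tested. Summed RPKM gave −0.26 for hydrogen peroxide-producing oxidases between poplar and PDA and −0.92 between glucose and PDA, −0.12 for pectinases between poplar and glucose, −0.35 for aromatic and xenobiotic conversion between glucose and PDA, and −0.16 for proteases between glucose and PDA. Cytochrome P450s between poplar and glucose had 0.31 summed and 0.17 at a minimum RPKM of 10. Signs also changed in 27 values of lists whose median lay inside that range, 34 in all. Of the other lists' values, 365 stayed within the counting interval, 60 moved and 7 reversed, and of single-gene log2 ratios 307 stayed and 62 moved. Depth limits genes with few reads most: of the listed gene models, 8429 in the PDA library, 8550 in the glucose library and 8702 in the poplar library had at least 10 reads.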

Other observations

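The grouping of the peroxidases by name was made only after their values were seen. The test described last was set before its result was seen.

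Genes with lignin peroxidase names did not all share 1 profile. The lignin peroxidase Trave1_43559 measured 70.3 RPKM in the PDA library, 562 in the glucose library and 333 in the poplar library, while Trave1_43848 measured 277, 41.3 and 219. The manganese-repressed peroxidase Trave1_26509 measured 146, 367 and 38.2 RPKM in that order, with a log2 ratio of −3.23 between poplar and glucose. These 3 genes were chosen after their values were seen. Summed over the manganese peroxidase names, RPKM was 488 in the PDA library, 457 in the glucose library and 951 in the poplar library. That group was drawn from all gene models and not from the class II list alone, and it leaves out the manganese-repressed Trave1_26509.

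The pheromone genes Trave1_45033 and Trave1_49815 were 4.25-fold (3.31 to 5.53) and 6.46-fold (2.25 to 25.4) higher in the poplar library than in the glucose library, while the pheromone gene Trave1_49829 was 3.55-fold lower (1.72 to 8.07). The hydrophobin Trave1_120575 was 10.8-fold lower (4.72 to 30.5) in the glucose library than in the PDA library. The chitinase Trave1_132063 was 5.79-fold (4.31 to 7.93) and 6.82-fold (5.01 to 9.48) higher in the poplar library than in the glucose and PDA libraries.

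A hypothesis was that the poplar profile lies between those of the other two media. Among 2018 genes that differed at least 2-fold between the glucose and PDA libraries, the poplar library lay between them in 63.9%. The like share was 51.5% of 1673 genes with glucose as the third library and 51.6% of 1745 genes with PDA as the third. The share with poplar in between thus exceeded the higher of the other shares by 12.2 percentage points. The differences between glucose and PDA were also the most numerous, which could itself raise this share. The excess therefore cannot decide against selection of genes by the outer libraries alone, and whether the poplar profile is partly intermediate stays open.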
